A study of Caenorhabditis elegans with 63 samples.

How the data were processed

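The series held 63 libraries of Caenorhabditis elegans embryos in 28 groups, and the authors deposited 1 pooled track per group, a list of replication origins and a list of replication timing domains. Chromatin endogenous cleavage (ChEC-seq) used micrococcal nuclease (MNase) fused to CDT-1 or TRES-1 and switched on with calcium in isolated embryonic nuclei, per the labels' protocols, so that DNA near the tagged protein was cleaved and sequenced. EdU-seq measured DNA that had taken up the thymidine analogue EdU, and Repli-seq measured DNA in fractions labelled early, mid and late, both on cells taken from embryos. Samples were grouped by the strain, temperature, fraction and time given in the labels. The wild type was N2, and the H3.3 null carried alleles of his-69, his-70, his-71, his-72 and his-74 per the labels. The labels did not say from which event the times of the EdU course were counted.

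Reads were aligned with Novoalign, per the submitters' processing notes. Its version, the genome build, and the filters and scaling were not given in the sources used here, so coordinates are those of the deposited files and no gene was assigned by position. Free MNase, genomic DNA and genomic DNA with HU (as labelled) were deposited as whole-number counts of reads per bin. Their totals were 125 M, 62.7 M and 66.8 M reads (M, mega). The nucleosomal MNase tracks of both genotypes were deposited as signal per bin of 100 bp that was never below 0, and each value was a whole multiple of a fixed step that corresponded to 216 M reads in wild type and 62.9 M in the H3.3 null. The other 23 tracks were deposited as differences centred near 0, in bins of 1 kb for ChEC-seq and EdU-seq and of 10 kb for Repli-seq, and their scale was inferred here from the values.

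Adding back a running mean over 5 bins of the matching control, scaled to 50 M reads, left 0 of the 23 tracks with a bin below 0, whereas a running mean over 3 bins left all 23 with such bins. The rebuilt tracks added to between 49.97 and 50.04 M. At least 99.99% of the rebuilt values in each track were whole numbers of reads within a tolerance of 0.05 of a read, which gave the number of reads behind each track. The values are therefore described as reads per 50 M minus the control, smoothed over 5 bins, with free MNase as control of ChEC-seq, genomic DNA with HU as control of EdU-seq and genomic DNA as control of Repli-seq. A genome-wide mean bin held 499 reads per 50 M at 1 kb and 4988 at 10 kb. Neighbouring bins share reads through the smoothing, so widths under about 5 kb cannot be resolved and windows of 1 kb and 2 kb differ little.

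The ChEC-seq tracks rested on 5.00 to 86.5 M reads, the EdU tracks on 27.9 to 182 M and the Repli-seq tracks on 19.5 to 62.1 M. The TRES-1 track at 20 °C was the shallowest, with 238 reads in a median 5-kb window, against 1273 to 9053 in the EdU tracks. Each group came as a single pooled track, so the spread between replicates could not be measured. No SD, SE or p-value is given, and differences between conditions are descriptions of these pooled libraries. Intervals over origins are interquartile ranges. The 95% Wilson interval of a share of bins covers counting error only and is too narrow, because neighbouring bins are not independent. PCR copies were not told apart from separate molecules.

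The design had assumed tracks on a log or linear scale. Since the deposited values are differences, all contrasts were computed as differences of reads per 50 M, and log2 ratios of rebuilt densities were added as alternatives. Replication timing was the early minus the late fraction in 10-kb bins, centred on the genome median of each genotype, so that positive values mean earlier replication. The genomic DNA control cancels in this difference. Origin-centred signal was the mean of the bins within 2 kb of the origin centre minus the mean of the bins 10 to 20 kb away on both sides. Origins were the authors' 1110 calls of 3 kb, in the classes Early, Late and Dormant as named in the deposited list. Centres lay at most 4 bp from the centre of a 1-kb bin. Nucleosomal signal was averaged within 200 bp of origin centres, and within 1 kb as an alternative.

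A class median was placed among 10000 random placements of as many sites on the same chromosomes, or, for differences between conditions, among 10000 random subsets of as many origins. A percentile below 2.5 or above 97.5 was called. Profiles were read out to 20 kb, with the height above the level at 15 to 20 kb, the distance at which the profile fell to 0.5 of that height, and the centre minus shoulders at 4 to 8 kb. The named regions followed a rule fixed in advance. It took per class the 3 origins with the highest EdU signal at 20 °C, and the 5 origins with the largest rise and the 5 with the largest fall in TRES-1 for temperature and for H3.3, among those whose EdU signal at 0 min moved the same way. It also took the 5 longest Early and Late domains and, per direction, the 5 10-kb bins with the largest timing shift whose neighbours shifted alike, at most 1 per 100 kb. Regions with genomic DNA counts under 0.5 or over 2 times the median were left out of the named origins and bins, which removed 309 origins from naming.

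The genotype labels were checked without gene models. Runs of at least 10 bins of 100 bp with nucleosomal signal under 10 in the H3.3 null and over 40 in wild type were listed. For each track, the rebuilt density over its control in the 5-kb window at a run was then compared with that in the bins 5 to 8 kb away, and the loss was divided by the share of the window that the run covered (84% for the longest run). The result is the percent of signal missing, near 0 if the DNA is present and near 100 if it is absent from the strain.

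On simulated tracks with known depths of 5 to 100 M reads, the number of reads was recovered within 1% in 20 of 20 simulations. In 200 simulations with no planted difference, the random-subset comparison on 312 origins called 4% for the H3.3 effect on EdU at 0 min and 25 °C. It called 10.5%, 35.5% and 95.5% with planted differences of 5, 10 and 20 reads per 50 M. The random-placement comparison, tested on EdU at 20 °C with 182 sites, called 5% with nothing planted and 18.5%, 62% and 99.5% with 5, 10 and 20 reads planted. Both comparisons were tested on sites drawn by their own random scheme, so the rates with nothing planted were set in advance. They do not cover any clustering of the real origins.

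Alternatives changed the window, the flanks, the mean or median over origins, isolated origins, genomic DNA limits, the scaling of tracks, the fractions behind timing and chromosome X. Gene lists, start sites and the H3.3 genes by position were not analysed, since a genome annotation of the build behind the files was not used here. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.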

Results

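The series set wild type C. elegans embryos beside embryos without the histone variant H3.3, which is placed into chromatin independently of DNA synthesis, and asked how its loss alters replication timing and replication origins. CDT-1, a licensing factor that helps load the replicative helicase, was mapped by ChEC-seq in 5 libraries at 20 °C. TRES-1 was mapped by ChEC-seq in 4 wild type libraries at 20 °C, 2 at 25 °C and 2 H3.3 null libraries at 25 °C. EdU incorporation was measured in 4 wild type libraries at 20 °C, and in a course of 0, 30 and 60 min with 2 libraries per time, temperature and genotype. Repli-seq at 25 °C had 2 early, 1 mid and 3 late libraries in wild type and 2 libraries per fraction in the H3.3 null. Nucleosomal MNase-seq at 25 °C had 3 libraries per genotype. Controls were 2 libraries of free MNase, 1 of genomic DNA and 1 of genomic DNA with HU, all labelled 20 °C and none labelled H3.3 null. The same controls were subtracted from the tracks at 25 °C and of the H3.3 null. They therefore do not correct for a background that differs between temperatures or genotypes. All libraries of a group were deposited as 1 pooled track, so the values below carry no replicate error, and quartiles refer to the spread over origins or bins. Depth of the 23 tracks given as differences from a control ran from 5.00 M reads for TRES-1 at 20 °C to 182 M for EdU at 20 °C, and the wild type nucleosomal track held 216 M.

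The genotype labels were checked at DNA that the H3.3 null strain lacked. In its nucleosomal track, 7 runs were empty that were covered in wild type, and the reverse occurred at 0 runs. The longest spanned 4.2 kb at V 4056301 to 4060500, where the mean signal was 94.0 in wild type and 1.06 in the H3.3 null. Others lay at III 4058101 to 4060100, III 12367301 to 12368300 and X 7981601 to 7982600, and the remaining 3 on I and II. Chromosomes III, V and X are those of the listed H3.3 alleles.

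At the longest run, which filled 84% of the smoothed window, TRES-1 in the H3.3 null lacked 97.2% of its signal, and the EdU tracks of the H3.3 null at 25 °C lacked 86.3 to 87.8%. The value was between -10.3 and 8.48% in the wild type EdU tracks at 25 °C, 5.00% for EdU at 20 °C outside the course and -20.0% for CDT-1, where values below 0 mean more signal than beside the run. TRES-1 at 25 °C in wild type lacked 0.0942%, and the shallow TRES-1 track at 20 °C lacked 37.4% with 171 reads in the window. The EdU course at 20 °C stood apart. The 3 tracks labelled wild type lacked 51.6 to 62.5%, and the 3 tracks labelled H3.3 null lacked 57.1 to 58.3%. Neither set matched its label at this run, so these 6 tracks are called by their labels throughout, and differences between them are not given as an effect of genotype. In Repli-seq, with coarser bins, the ratio of H3.3 null over wild type in the 5 bins around this run was 0.915 of that in the next bins. Empty DNA was calculated to give 0.916. Taken singly, the signal was 0.967 of the next bins in wild type and 0.885 in the H3.3 null.

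The other 6 runs filled 20 to 40% of the window, and their values scattered widely, from -58.9 to 174% in the H3.3 null EdU track at 30 min and 25 °C. Over the 7 runs the median was 113% for TRES-1 in the H3.3 null and 86.4, 87.8 and 28.3% for its EdU tracks at 0, 30 and 60 min and 25 °C. In wild type at 25 °C it was -10.3, 6.19 and 23.1%, so by this measure the genotypes were not separated at 60 min. In the EdU course at 20 °C it was 59.1 to 74.5% for the labelled wild type and 57.7 to 74.6% for the labelled H3.3 null. The mean ratio of H3.3 null over wild type EdU at the 7 runs was 0.687, 0.846 and 0.785 at 25 °C, and 1.06, 1.06 and 1.00 for the tracks so labelled at 20 °C.

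**Figure D1:**
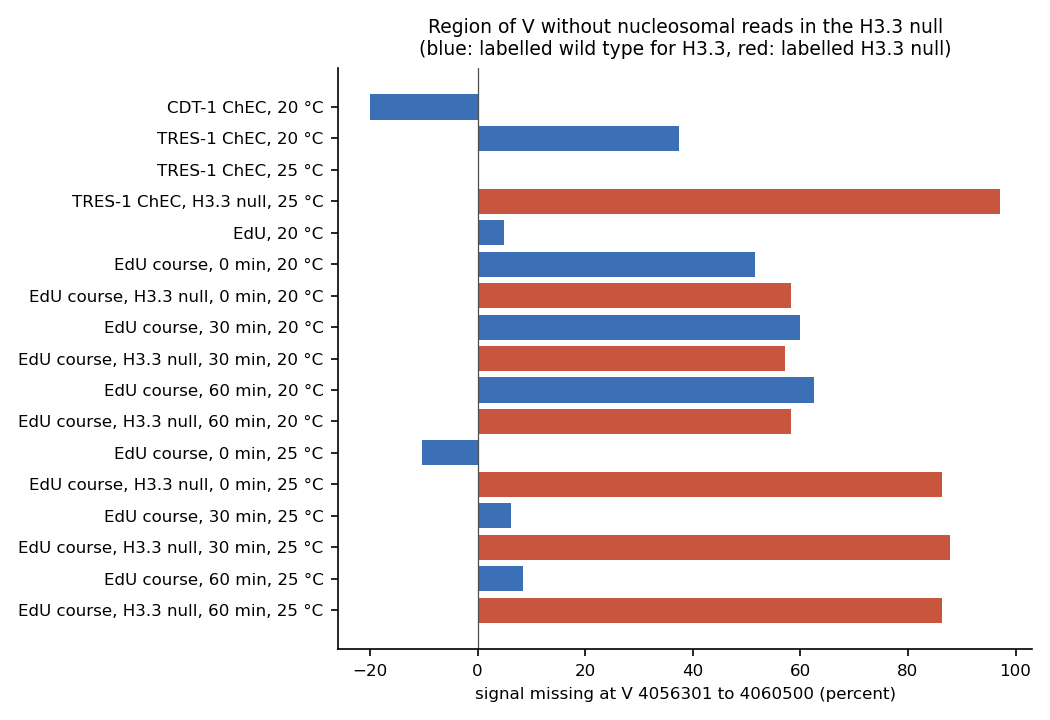
Percent of signal missing at the longest run that is empty in the H3.3 null nucleosomal track (V 4056301 to 4060500), for each pooled track labelled wild type for H3.3 (blue) or H3.3 null (red). At 25 °C both genotypes separate at this run, though not by the median of all 7 runs at 60 min (28.3 and 23.1%), whereas the 6 tracks of the EdU course at 20 °C all lie between 51.6 and 62.5%.

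Wild type embryos replicated chromosomes I and III early and chromosome V late. Median timing, as early minus late reads per 50 M in 10-kb bins, was 2278 on I, 2220 on III, 491 on II, -153 on X, -960 on IV and -3325 on V. Each chromosome was cut into 3 equal parts, and over all chromosomes together the middle parts were earlier than the outer parts (median 1110 against -495). The contrast was clear on III, with 3122 in the middle and 1393 outside. On X it went the other way by a small amount, with -224 in the middle and -86.6 outside. With early and mid fractions in place of early and late, the median of II fell to -297. Over the alternatives other than log2 ratios, the medians of I and III fell as low as 618 and 501. That of V rose as high as -9.12, so the sizes of these contrasts depended on the setting.

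The deposited list split the genome into 189 Early domains covering 52.44 Mb and 188 Late domains covering 44.51 Mb, with median lengths of 170 kb and 130 kb. Early domains took 80.4% of the domain length on I, 79.9% on III and 22.8% on V. The longest Early domain lay at III 3390001 to 6670000, spanned 3280 kb, held 50 origins and had a median timing of 3254. The next were III 7510001 to 9290000, I 5070001 to 6630000, III 9400001 to 10950000 and I 7420001 to 8880000, with median timing of 3154, 2931, 2812 and 3017. The longest Late domain lay at V 15110001 to 18070000, spanned 2960 kb, held 12 origins and had a median timing of -5015. It was followed by V 1630001 to 3440000, IV 15060001 to 16350000, X 8700001 to 9890000 and V 18120001 to 19210000, with -5133, -5325, -2498 and -4995. The domain on IV held 1 origin.

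Embryos without H3.3 kept the wild type order of early and late regions, over a narrower range in the genome and in Early domains. Across 10023 bins the timing of both genotypes had a rank correlation of 0.982 and a Pearson correlation of 0.951, and bins are not independent replicates. The sign was the same in 95.4% of bins (Wilson interval 94.98 to 95.80%). The interquartile range was 5328 in wild type and 4220 in the H3.3 null, a ratio of 0.792. Within Early domains the ratio was 0.730, whereas it was 1.03 within Late domains and 0.986 on chromosome V. Early domains moved from a median of 2184 to 1582, with a median shift of -565 (quartiles -1025 to -148), and Late domains from -3151 to -2702, with a median shift of 222 (quartiles -202 to 642). With early and mid fractions the genome-wide ratio was 1.02 and the shift in Early domains was 11.6. Taken singly, the fractions had interquartile ranges of 2840.25 in wild type and 2289.8 in the H3.3 null for early, 1959 and 2091 for mid, and 2368 and 2006 for late, with a wild type mid fraction from 1 library.

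Chromosomes differed in how far they moved. The median went from 2278 to 1753 on I, from 2220 to 1675 on III and from -3325 to -2848 on V. On II and X it went away from 0, from 491 to 622 on II and from -153 to -399 on X. Taken bin by bin, the median shift was -478 on I, -374 on III and -367 on X. It was 4.29 on II, -3.18 on IV and -18.9 on V (quartiles -487 to 471 on V). By this paired measure II, IV and V did not move as a whole. On X 124 bins passed from early in wild type to late in the H3.3 null and 19 passed the other way, whereas on II 19 bins became late and 64 became early. Early domains on X had a median shift of -722, and those on V -355. Among the longest Late domains, V 15110001 to 18070000 went from -5015 to -5609 and IV 15060001 to 16350000 from -5325 to -5933, so that these regions were later in the H3.3 null, while the longest Early domain on III went from 3254 to 2550.

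**Figure D2:**
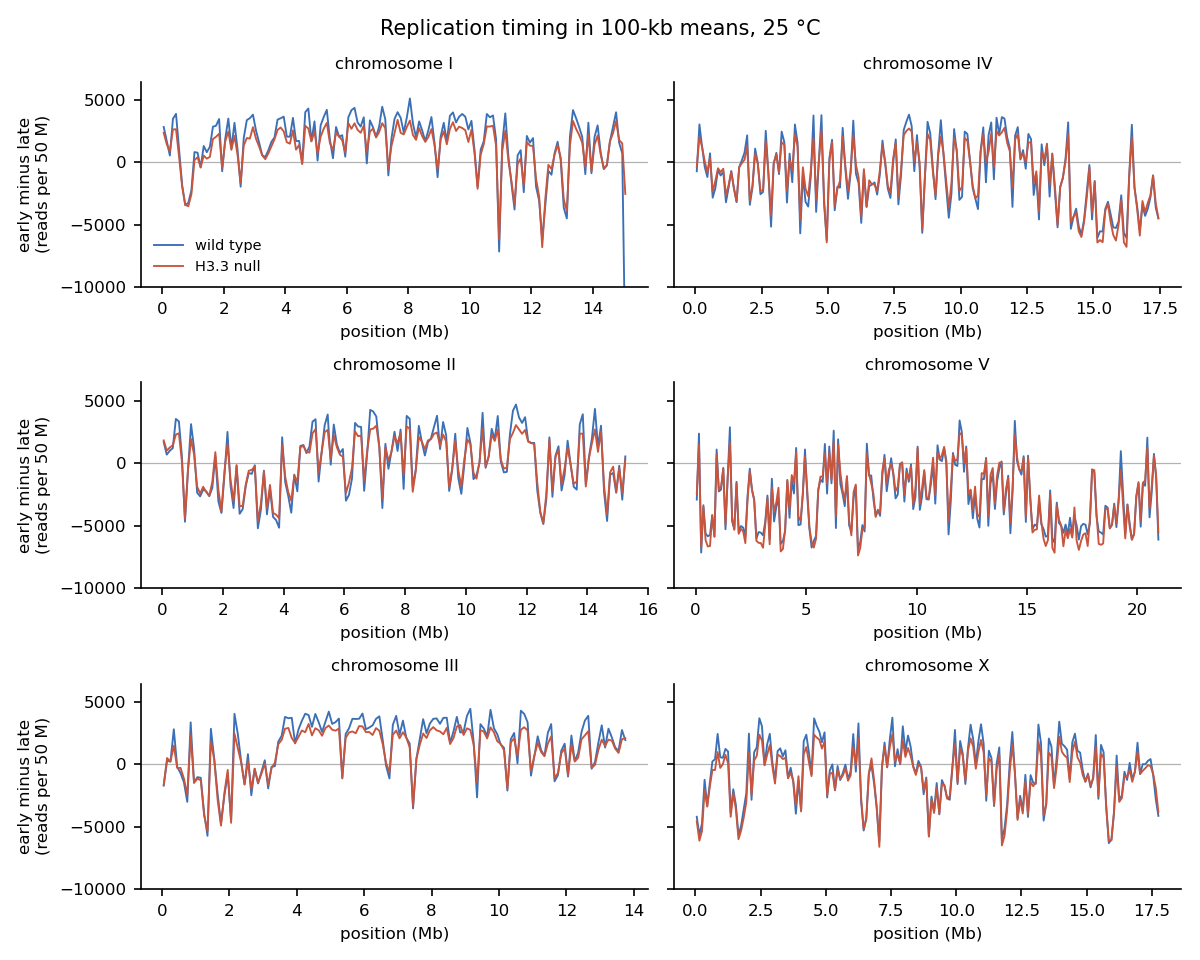
Early minus late Repli-seq signal (reads per 50 M and 10-kb bin, means over 100 kb) along the 6 chromosomes in wild type (blue) and H3.3 null (red) at 25 °C, against position in Mb. Both lines follow the same peaks and troughs over a range that is narrower in the H3.3 null in the genome as a whole (interquartile ratio 0.792), and the last wild type bins of I run below the axis.

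Among bins that met the rule for naming, those with the largest single shifts lay in both kinds of domain. The largest shift to earlier replication in the H3.3 null was at IV 10960001 to 10970000, from -5283 to -1489 in a Late domain, and there the late fraction went from 3527 to -286. Next came III 8860001 to 8870000, from 605 to 3080.4, and II 5120001 to 5130000, from -5249 to -2990. IV 13340001 to 13350000 and IV 11970001 to 11980000 gained 2003 and 1823. The largest shifts to later replication were at V 16680001 to 16690000, from -9124 to -12304, IV 4430001 to 4440000, from 4091 to 1361, and X 11790001 to 11800000, from -8076 to -10676. III 13050001 to 13060000 and I 4000001 to 4010000 followed with shifts of -2529 and -2470.

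The deposited origins numbered 1110, of which 182 were Early, 616 Late and 312 Dormant. Their density was 11.1 per Mb, and it was highest on I at 15.7 per Mb and lowest on V at 7.22 per Mb. Late origins made up 74.3% of the origins on X and 55.5% of those in the genome. Early origins lay inside Early domains in 89.0% of cases and Late origins in 74.4%, against medians of 57.7% and 56.3% in random placements (percentile 100 for both). Dormant origins were in Early domains in 54.2% of cases, against 58.3% at random (percentile 5.92). How the authors made the classes is not given in the sources used here, and tracks of this series were probably used, so these shares are no independent test.

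Early origins lay near one another. The median distance from an Early origin to the next Early origin was 102.5 kb, against 182 kb in random placements (percentile 0). Dormant origins lay farther from Early origins, at 291 kb against 223 kb (percentile 99.95), and the distance between Dormant origins was 90.5 kb against 98.1 kb (percentile 20.2). In wild type, the 10-kb bins of Early origins had a median timing of 2963 (quartiles 2169.6 to 3598) and those of Late origins 2125 (349.8 to 3209), both above random placements (percentile 100). Dormant origin bins were at 385, within random placements (percentile 9.98). In the H3.3 null these medians were 1577, 1385 and 269.

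CDT-1 and TRES-1 signals ranked the classes of origin in opposite orders in wild type at 20 °C. CDT-1 signal was highest at Dormant origins, with a median of 158 reads per 50 M and 1-kb bin over the flanks (quartiles 111 to 198), followed by Late origins at 117 (60.4 to 167) and Early origins at 51.7 (-25.2 to 153). It was above the flanks at 99.7% of Dormant origins. TRES-1 signal ran the other way, with 200.5 at Early origins (90.1 to 284), 138 at Late origins (74.4 to 203) and -2.22 at Dormant origins (-44.2 to 41.4). The percentile among random placements was 100 in each of these cases except TRES-1 at Dormant origins, where it was 71.9. EdU at 20 °C was above the flanks at Early origins (84.5, quartiles 11.4 to 158) and below them at Late (-34.95) and Dormant origins (-74.7). If these tracks served to make the classes, that choice fixes the contrasts between classes at least in part, and the percentiles are then no test of them.

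Part of these values came from the controls that the authors subtracted. Free MNase itself was 59.3 above its flanks at Early origins and -28.6 at Dormant origins, and genomic DNA with HU was 3.12 at Early, 20.7 at Late and 46.2 at Dormant origins. The HU values depended on the setting, from 0.316 to 52.0 at Early, 5.03 to 40.2 at Late and 23.8 to 56.6 at Dormant origins over the alternatives. With the smoothed control added back, CDT-1 was 104 at Early, 111 at Late and 137 at Dormant origins, TRES-1 was 254, 127 and -19.8, and EdU was 96.4, -16.2 and -35.2. The order of the classes was the same on both scales. The CDT-1 peak fell to 0.5 of its height at 3.21 kb from Dormant origins, and the EdU peak at 7.10 kb from Early origins.

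**Figure D3:**
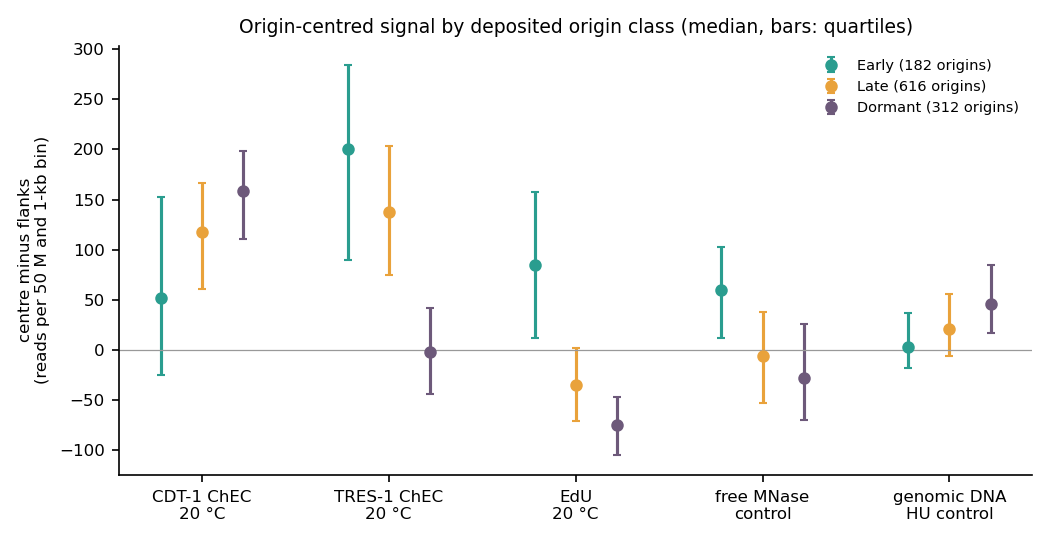
Median origin-centred signal (centre minus flanks, reads per 50 M and 1-kb bin) of CDT-1, TRES-1 and EdU in wild type at 20 °C and of both controls, by origin class, with bars from the lower to the upper quartile over origins. CDT-1 rises from 51.7 at Early to 158 at Dormant origins, and TRES-1 runs from 200.5 at Early to -2.22 at Dormant origins.

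Single origins did not all follow their class. Within the genomic DNA limits, the highest EdU signals of the Early class were 333 at IV 5074001 to 5077000, 280.3 at I 13376001 to 13379000 and 269 at I 3844001 to 3847000. TRES-1 was 86.6, 107 and -48.4 there. Those of the Late class were 121 at X 10765001 to 10768000, 116 at V 12185001 to 12188000 and 109.9 at II 5459001 to 5462000, where TRES-1 was 263, 217 and 251. The Dormant class reached 69.9 at III 11872001 to 11875000, 36.9 at II 3518001 to 3521000 and 24.9 at II 1746001 to 1749000, with TRES-1 at -85.7, 5.30 and 71.05. These origins were picked for their EdU, and among them TRES-1 was higher in the Late than in the Early class, the reverse of the class medians.

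TRES-1 was higher at Dormant origins at 25 °C than at 20 °C in wild type, with small differences at the other classes. Dormant origins went from -2.22 to 38.2, with a median difference of 41.4 (quartiles 0.552 to 76.1), higher at 76.0% of origins and on 6 of 6 chromosomes (percentile 100 among random subsets of origins). Early origins differed by 2.27 (percentile 2.85) and Late origins by 1.61 (percentile 0, a smaller change than that of all origins, 12.8), with 3 of 6 chromosome medians above 0 for Late origins. The Early value turned its sign and was called with means over origins (-5.81, percentile 1.40), with isolated origins (-3.58, percentile 0.640) and as a log2 ratio (-0.012, percentile 0.255), so its direction was not settled. The 20 °C track is the shallowest of the series. If it served to make the classes, that choice may fix the difference at Dormant origins in part, and the percentile is then no test of it.

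The single origins given next met the rule for naming. It kept origins whose EdU at 0 min moved the same way, measured against the 20 °C track labelled wild type. Among them, TRES-1 was higher at 25 °C by 376 at the Early origin II 6829001 to 6832000. It was higher by 276 at the Late origin V 3757001 to 3760000 and by 248 at the Early origin I 7712001 to 7715000. V 11947001 to 11950000 and II 14249001 to 14252000 differed by 234 and 233. At the Early origin X 10365001 to 10368000 it fell by 815, from 1050.4 to 235, and at X 1884001 to 1887000, V 20921001 to 20924000, III 11931001 to 11934000 and I 453001 to 456000 the differences were -328, -308.5, -250.4 and -246. EdU at 0 min, measured against the 20 °C track labelled wild type, differed by 34.6 at Early, 8.02 at Late and -1.34 at Dormant origins. That track did not match its label at the longest run. Against the EdU track of the other wild type group at 20 °C, the Early difference was 22.8, the Late difference -13.8 and the Dormant difference -10.9.

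Without H3.3, TRES-1 signal at 25 °C kept its order of classes, with 158 at Early, 134 at Late and 53.0 at Dormant origins, and small shifts between them. Early origins were lower, from 195 to 158 with a median difference of -14.4 (quartiles -40.8 to 5.58), and 0 of 6 chromosome medians were higher. Dormant origins were higher, from 38.2 to 53.0 with a difference of 15.5 (quartiles -0.506 to 31.1), on 6 of 6 chromosomes. Late origins differed by 4.71. Among random subsets of origins the percentiles were 0, 100 and 21.2. If wild type tracks of this series served to make the classes, that choice may fix these differences in part. The percentiles are then no test of them. With tracks scaled to the same interquartile range the differences were -43.2, 5.99 and -16.3 (percentiles 0, 100 and 0), so the direction at Late origins was not settled. The call at Dormant origins ended without the flanks, where the difference was 2.24 (percentile 40.8), and with the mean in place of the median (16.8, percentile 94.9).

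Among origins that met the rule for naming, TRES-1 was higher without H3.3 by 104 at the Late origin X 4809001 to 4812000. It was higher by 87.2 at the Dormant origin X 12848001 to 12851000 and by 84.9 at the Late origin II 6845001 to 6848000. The Dormant origins V 6884001 to 6887000 and II 11298001 to 11301000 followed with 84.2 and 81.4. By the same rule, the lowest difference was -159 at the Early origin I 7473001 to 7476000. Next came -122 at I 14719001 to 14722000, -119 at X 11606001 to 11609000, -98.2 at X 17715001 to 17718000 and -94.5 at II 9283001 to 9286000, these 4 of the Late class.

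The largest contrast between genotypes was EdU at Dormant origins at 25 °C. After 30 min, wild type embryos were below the flanks there (-39.2) and H3.3 null embryos far above them (274). The median difference was 312 reads per 50 M (quartiles 202 to 447), against a mean bin of 499, and it was positive at 97.8% of the 312 origins and on 6 of 6 chromosomes (percentile 100). Late origins differed by 155 (23.8 to 263), and Early origins by -10.6 (-158 to 99.4). After 60 min the differences were 153 at Dormant, 72.5 at Late and -9.33 at Early origins. At 0 min they were 77.5, 63.6 and 50.3, and each class was higher without H3.3 on 6 of 6 chromosomes. If tracks of this series served to make the classes, that choice may fix the contrasts between classes in part. The percentile is then no test of them.

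In the H3.3 null after 30 min, EdU peaked at Dormant origins 313 above the level at 15 to 20 kb and fell to 0.5 of that at 3.33 kb. The centre exceeded the shoulders by 221 at Dormant and 110 at Late origins, whereas in wild type the centre minus shoulders was -21.5 and -17.8. The difference was similar for Dormant origins in Early domains (293) and in Late domains (333). For Early origins it was 9.43 in Early domains (162 origins) and -279 in Late domains (12 origins). With the control added back, Dormant origins stood at 1.47 in wild type and 306 in the H3.3 null. At 0 min, the EdU peak of Early origins had a height of 134 in wild type and 184 in the H3.3 null, with distances to 0.5 of the height of 6.16 and 7.16 kb. The Early differences after 30 and 60 min did not keep their sign under all settings. The H3.3 null track at 30 min was the shallowest of the course, with 27.9 M reads against 79.4 M in wild type.

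**Figure D4:**
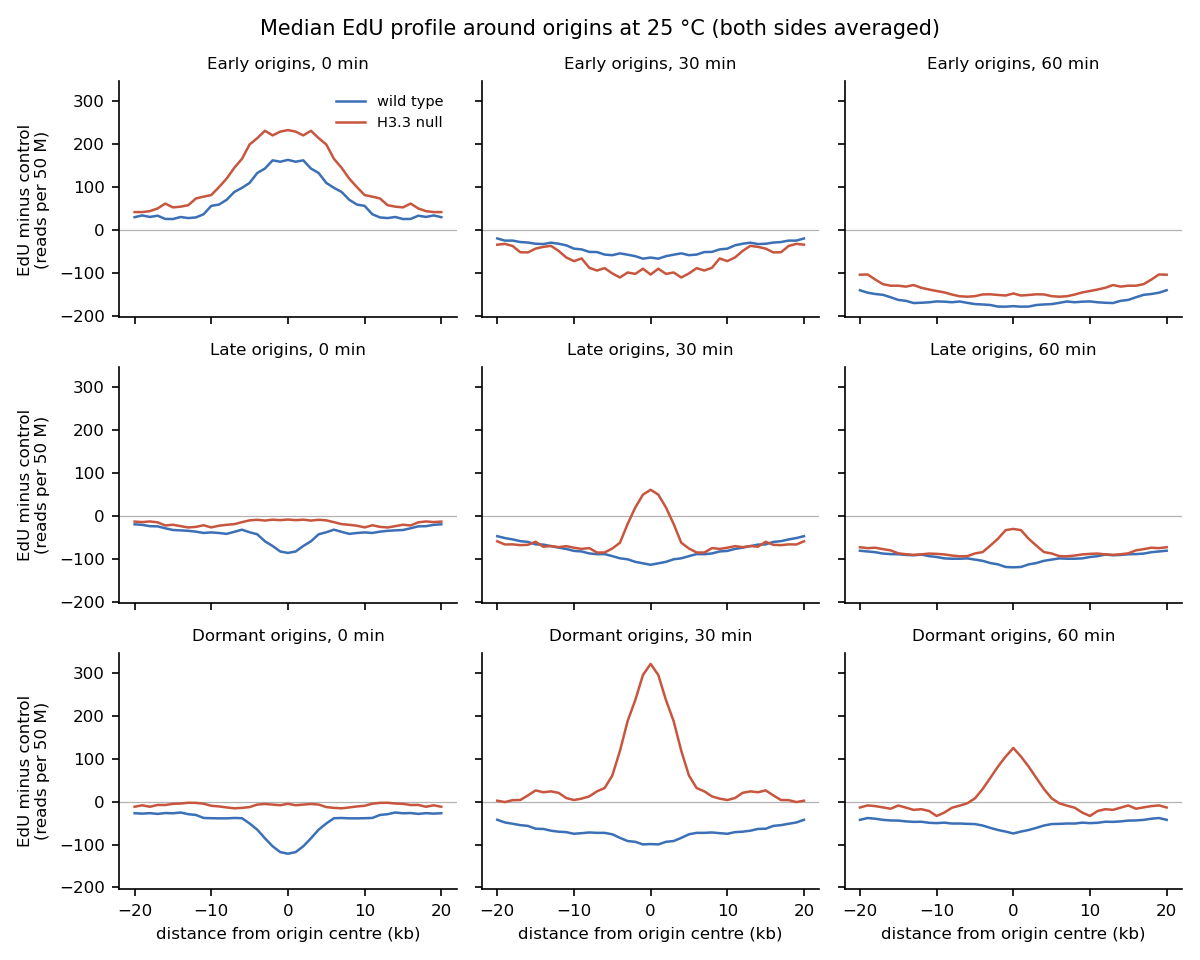
Median EdU signal minus control (reads per 50 M and 1-kb bin) against the distance from the origin centre in kb, for each origin class and time at 25 °C, in wild type (blue) and H3.3 null (red), with both sides of the origin averaged. After 30 min the H3.3 null profile stands 313 above its surroundings at Dormant origins, where the wild type profile has no peak.

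At 20 °C the tracks labelled H3.3 null and wild type differed little. The differences at Early, Late and Dormant origins were -30.9, -3.51 and -16.8 at 0 min, -0.908, 8.79 and 20.3 after 30 min, and -1.69, -6.22 and -1.002 after 60 min. These tracks did not match their labels at the longest run, so the small differences are no measure of H3.3 loss at 20 °C.

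**Figure D5:**
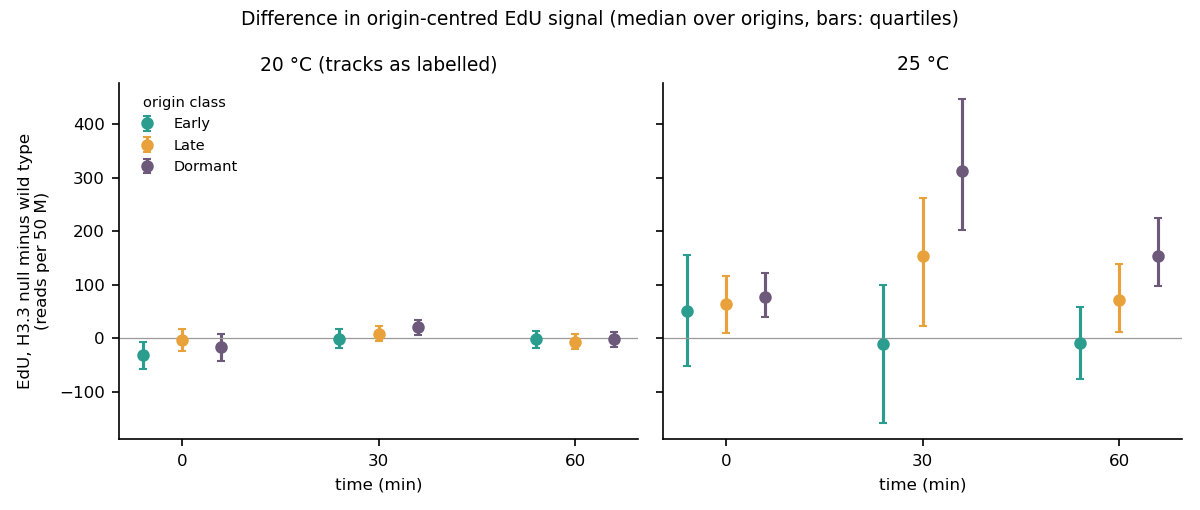
EdU in the H3.3 null minus wild type (median over origins of the origin-centred signal, reads per 50 M, bars from lower to upper quartile) by origin class and time at 20 °C, as labelled, and at 25 °C. Dormant origins at 25 °C reach 312 after 30 min, and no class differs by more than 30.9 in size at 20 °C.

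Nucleosomal signal at origins was close between genotypes. Within 200 bp of Early origins the median was 104 in wild type and 112 in the H3.3 null, with a difference of 7.19 (quartiles -6.09 to 20.1), higher at 64.8% of origins. Late origins were at 91.8 and 93.4, with a difference of 3.15 (-7.27 to 13.4), and Dormant origins at 92.7 and 92.0, with a difference of -1.26 (-9.14 to 8.45). The difference was above random placements at Early and Late origins (percentile 100 for both) and within them at Dormant origins (percentile 57.2). Late and Dormant origins had less nucleosomal signal than random sites in wild type (percentiles 0 and 0.22). Mitochondrial DNA made up 0.538% of the wild type signal and 1.07% of the H3.3 null signal.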

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

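The tests of the 20 °C tracks given here were all chosen after the result was seen. The H3.3 null minus wild type difference in EdU at origins had opposite directions at the 2 temperatures in 3 cases, on 0 of 6 chromosomes higher at 20 °C and on 6 of 6 at 25 °C. At Early origins at 0 min it was -30.9 at 20 °C and 50.3 at 25 °C, 81.2 apart. At Dormant origins at 0 min it was -16.8 and 77.5, 94.2 apart, and at Late origins after 60 min it was -6.22 and 72.5, 78.7 apart. With 1 pooled track per group these differences between temperatures were not tested.

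Behind these cases lies a wider pattern, that the EdU tracks of both genotypes were nearly alike at 20 °C, with rank correlations over 10-kb bins of 0.861, 0.981 and 0.976 at 0, 30 and 60 min, and apart at 25 °C, with 0.649, 0.374 and 0.719. Simulated tracks drawn from the control alone, with no EdU signal, shared only the subtracted control. In 100 simulations they gave mean rank correlations of 0.384 to 0.521. Their covariances were 37.1 to 37.3, against observed covariances of 2606 to 27129. These values show what the shared control gives, and not how alike equal EdU signals would be. At 30 min and 25 °C the observed rank correlation of 0.374 was no higher than the simulated 0.384. It was 0.373 with the control added back, so it did not hang on the subtraction. The simulated value came from the noise of the shared control alone and is no yardstick for the EdU signal that these tracks share. An exchange of whole labels was excluded at the longest run absent from the H3.3 null strain, where the tracks labelled wild type lacked at most 62.5% of the signal and those labelled H3.3 null at least 57.1%, and exchanged tracks would lack nearly all and nearly none. A mix of reads of both genotypes in each 20 °C course track may account for the pattern but was not decided, since at that run all 6 lacked at least 51.6% and none as much as the 86.3% of H3.3 null tracks at 25 °C, while by the median of 7 runs they lacked 57.7 to 74.6% and an H3.3 null track at 25 °C only 28.3%. Whether H3.3 loss acts on EdU at 25 °C and not at 20 °C cannot be told apart from this, because the tracks labelled H3.3 null lacked at most 58.3% at the longest run, and a test would need tracks of a single genotype.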

How the results depend on the processing

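The log2 scales of rebuilt densities, the control added back and the EdU track of the other wild type group were chosen after seeing the data, and the other alternatives before the data were examined. Of 569 values of 78 results under alternatives, 498 were counted as the same, 23 as weaker, 10 as stronger, 2 as moved and 36 as reversed. For results with a percentile, the same meant the same side of the middle of the draws and the same call. Results without a percentile were judged by the sign of the value, by which genotype had the narrower range, or by the Wilson interval. The rank correlation of timing was counted as the same under each alternative without a test. TRES-1 over all origins at 20 °C kept its call in 9 of 9 alternatives (72.6 to 132 in reads per 50 M), as did the TRES-1 difference with temperature at Dormant origins (25.9 to 43.2) and the H3.3 difference in EdU at Dormant origins after 30 min at 25 °C (207 to 397). The value itself turned its sign in 27 cases, 10 of them not among the reversed. Values below that reversed did so either in sign or by passing the middle of the random draws, 13 of them with no call on either side, and the cause was not tested.

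Without flanks, the H3.3 difference in TRES-1 was 2.24 at Dormant origins, no longer called, and 5.74 at Late origins, and with means over origins the Dormant value was 16.8, also no longer called. With the same interquartile range it was -43.2 at Early and 5.99 at Dormant origins, and it turned to -16.3 at Late origins, where a window of 5 kb gave 4.10, means 8.87 and leaving out chromosome X 6.07. The temperature difference in TRES-1 at Early origins turned to -5.81 with means, to -3.58 with isolated origins and to -0.012 as a log2 ratio, all called, and was 13.5 in a window of 5 kb. The H3.3 difference in EdU without flanks was 43.0 at Early origins after 60 min at 25 °C, and for the tracks so labelled at 20 °C it was -6.73 at Dormant origins at 0 min and 19.1 at Early origins after 30 min. With the same interquartile range the difference in EdU was 13.4 at Early origins after 30 min at 25 °C, and at 20 °C -23.1 at Early origins at 0 min, -6.30 at Late origins after 30 min, and -0.736 at Early and 6.24 at Dormant origins after 60 min. At Late origins at 0 min and 25 °C it was 72.9 without chromosome X. In a window of 5 kb it was 48.0 at Early origins at 0 min and 25 °C and 0.803 at Late origins at 0 min and 20 °C. As log2 ratios of rebuilt densities it was 0.033 and 0.0084 at Early origins after 30 and 60 min at 25 °C. The temperature difference in TRES-1 at Late origins was -0.165 with isolated origins, -0.217 without chromosome X and -0.0021 as a log2 ratio. That in EdU at Dormant origins was 0.619 within genomic DNA limits and 6.17 with the same interquartile range, and at Late origins 10.05 in a window of 5 kb, 9.56 with isolated origins, 11.7 with the same interquartile range and 0.024 as a log2 ratio. TRES-1 at Dormant origins at 20 °C was -2.36 with means, the HU control at Early origins 2.41 without chromosome X, and the nucleosomal difference at Dormant origins -0.972 at equal means.

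With early and mid fractions, timing had the same sign in both genotypes in 94.4% of bins, and without chromosome X in 96.5%. The former also put the median of II at -297 in wild type and -224 in the H3.3 null, that of V at 74.1 in the H3.3 null, the ratio of interquartile ranges at 1.02 and the shift in Early domains at 11.6. The mid fraction of wild type came from 1 library.

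No paired analysis was possible because each group was deposited as 1 pooled track, and leaving out replicates could not be done for the same reason. Placements on start sites, windows around start sites, gene lists, the H3.3 genes by position, the upper part of origins by score and the pseudocount on the deposited tracks were planned and not run. Depth limits single origins most in TRES-1 at 20 °C, with 238 reads in a median window.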

Other observations

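The tests of the wild type and CDT-1 signal at Dormant origins, of more reads of any kind, of the control behind the EdU dip, of a shrinking factor and of the shift of labelling were chosen after the result was seen. EdU moved toward later replicating DNA over the course. At 25 °C in wild type, the rank correlation of EdU with timing over 10-kb bins was -0.262 at 0 min, -0.517 after 30 min and -0.806 after 60 min, and Late domains exceeded Early domains by 34.0, 98.5 and 148 reads per 50 M. In the H3.3 null at 25 °C the correlations were -0.0578, -0.251 and -0.565. The correlation fell at both steps in 4 of 4 courses, as a shift of labelling from early to late regions would need. This fall restates the pattern and is no separate test of such a shift. The 20 °C tracks also did not match their labels. Genomic DNA with HU, which is subtracted, had a correlation of 0.508 with timing itself. With the control added back, the correlations at 25 °C were 0.0527, -0.287 and -0.616 in wild type and 0.209, -0.0878 and -0.378 in the H3.3 null. Late minus Early domains was then -10.6, 49.8 and 113 in wild type, so the direction at 0 min depended on the subtraction.

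Among origins of a class, EdU of the H3.3 null after 30 min at 25 °C followed the wild type CDT-1 signal, with rank correlations of 0.740 at Early, 0.637 at Late and 0.472 at Dormant origins. With TRES-1 of the H3.3 null at 25 °C the correlations were 0.518, 0.0589 and -0.181. Origins are not independent replicates, and CDT-1 was measured at 20 °C.

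The EdU signal at Dormant origins of the H3.3 null after 30 min at 25 °C was weighed further, since it was higher than in wild type at 97.8% of these origins, which excludes a few origins as its source. Whether the track holds some wild type reads stays open. Its ratio of 0.846 over wild type at the 7 runs absent from the H3.3 null lay under a bound of 1.06, which came from 20 °C tracks of doubtful genotype. It lay above the other H3.3 null EdU tracks at 25 °C (0.687 and 0.785), but was not corrected for the flanks or the window share. At the longest run, the track lacked 87.8%, against 86.4 and 86.3% in those tracks at 0 and 60 min. That run gave no sign of more wild type reads than in those tracks. At the level of pooled tracks, such reads were argued against as the source of the peak. Wild type tracks other than CDT-1 reached at most 38.2 at these origins, under the H3.3 null lower quartile of 147. CDT-1 itself lay 115.6 below the H3.3 null, where at most 39.9 was allowed. A single library with a stronger signal than its pool is not excluded by this. The track also followed CDT-1 over origins of each class, with rank correlations of 0.472 to 0.740. More reads of any kind from these origins was argued against by a nucleosomal ratio of 0.994, under the bound of 1.2. A candidate explanation is that origins which take up little EdU in wild type take up more of it without H3.3. The differences at 0 and 60 min were lower (77.5 and 153). This explanation stays a hypothesis, since the track pools 2 libraries, has the lowest depth of the course and was not set against other H3.3 null strains.

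The narrower genome-wide range of timing in the H3.3 null was tested against 1 shrinking factor for all bins, as from less pure fractions. Within genomic DNA limits, the slopes of H3.3 null on wild type timing ran from 0.762 on I to 0.954 on V, a range of 23.02% of their mean (60.5% without the limits), where a single factor allowed under 10%. A single factor is therefore excluded as the whole cause, and purity that acts unevenly along the genome, as well as an effect of H3.3 loss, stays open and untested.

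By early minus late fractions, Early origins became later than the timing of their bins foretold. Their bins shifted by a median of -1298 in the H3.3 null, against -777 (-858 to -688) in bins of equal wild type timing. This was at percentile 0 of 10000 matched draws, which argued against an equal shift in both sets of bins. The draws were not matched on chromosome and took bins as independent. The comparison was not run with early and mid fractions, which put the shift in Early domains at 11.6. Late origin bins shifted by -684 against -504 (percentile 0), and Dormant origin bins by -262 against -216 (percentile 10.9). That TRES-1 and EdU at 0 min would change together at origins of each class was not borne out, with a lowest rank correlation of -0.0811 and 1 class above 0.2. Of the wild type EdU dip at Dormant origins at 0 min and 25 °C, 47.2% was left with the control added back. The control alone rose by 46.3% of the dip. By these values the control made up a part of the dip and not the whole, and neither bound set for a verdict was met.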
